A study of Homo sapiens with 6 samples.

How the data were processed

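The study measured messenger RNA in MV4-11 cells, a human acute myeloid leukemia line that carries an internal tandem duplication of the receptor kinase gene FLT3 and a KMT2A-AFF1 fusion. Cells were treated for 24 h with venetoclax at 100 nM, with cyclosporine A (CSA) at 2.5 µM, or with the combination, whose doses the labels do not give separately. These doses are from the growth protocol in the labels; the treatment entry of each sample names gavage, a route used in animals, and was not used here. Venetoclax is an inhibitor of the survival protein BCL2, and CSA is a calcineurin inhibitor that binds cyclophilins. There were 2 libraries per group and 6 in all, grouped by their titles. The deposited table also holds 2 columns that no label used here assigns to a sample. They were not used, so no comparison with untreated cells and no test of drug interaction was made. Nothing in the labels says that the replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

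Per the labels' protocols, total RNA was extracted with Trizol, libraries were made with the KAPA RNA HyperPrep kit and reads were paired, 150 bp long. Per the submitters' processing notes, STAR, RSEM and DESeq2 were used with the human build hg38. The notes give no versions or roles, and whether counting used strand is not given in the sources used here. The deposited values are whole-number counts per gene, not normalized, for 20263 Ensembl gene identifiers, and every entry named a gene. In each library 64.8% to 66.7% of the counts between 1 and 20 were even numbers, against 49.0% to 51.0% of the counts of 100 or more. With such an excess a count may not always be a single independent read pair, and low counts may carry more sampling error than a count model assumes. Of the identifiers, 20148 matched the symbol table and 20224 matched GENCODE release 29 (GRCh38), from which coordinates were taken. No count was present in any of the 6 libraries for 4656 genes.

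Total counts per library ranged from 26567900 to 30738957, and 13616 to 14252 genes had a count. Genes passing edgeR's filterByExpr (12690) were scaled by trimmed mean of M-values (TMM) and tested with edgeR 4.0.16 in R 4.3.3 (robust glmQLFit and glmQLFTest, two-sided) in a single fit of the 6 libraries by group, with 3 residual degrees of freedom. The 3 contrasts were combination against venetoclax, combination against CSA and venetoclax against CSA. P-values were adjusted by Benjamini-Hochberg and the threshold was 0.05. Errors of log2 fold changes are standard errors (SE) from this fit, and CPM, the usual depth-scaled count, is scaled by TMM unless called unscaled. Scaling by library size alone moved the median log2 fold change of all genes to 0.26, −0.04 and −0.31 in the 3 contrasts, so changes are given relative to the TMM scale.

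Gene lists (33, from textbook knowledge), the genes to be named and the contrasts were chosen before the data were examined. Lists with at least 3 tested members (32) were tested with camera from limma 3.58.1 at its preset inter-gene correlation of 0.01, with camera at an estimated correlation and with fry beside it. Camera asks whether a list ranks above or below all other genes, and fry asks whether its members move on balance one way. The rule for named genes took, per contrast, up to 12 genes in each direction with the largest fold change among those with adjusted p under 0.05, mean CPM of at least 5 and separated replicates. It also took up to 4 members with the smallest p of each list past camera, and 13 set genes. With all 6 libraries no gene met the first part of the rule. It was then applied to the fit without venetoclax replicate 2, a use chosen after the values were seen, as was every gene named outside the rule. Some genes that the rule takes are not reported here.

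Alternatives set in advance were DESeq2 1.42.0, limma-voom, other scalings and filters, a fit of only the 4 libraries compared, a replicate block, a minimum fold change of 1.5, and leaving out each library in turn. Alternatives added after seeing the data were removal of mitochondrially encoded genes, limma-voom with library quality weights, DESeq2 or a replicate block without venetoclax replicate 2, and removal of each library's trend with GC content (loess, span 0.3, over 12680 genes with a GC value). When a library was left out, the remaining library of its group was assumed to vary like the other groups. Overlap of calls against both agents was set beside 40 simulated draws of unchanged groups that share the combination libraries, and beside the overlap of independent lists.

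The tests were checked on simulated counts drawn with the means and library sizes of these samples, with 200 genes changed. At the spread of all 6 libraries the fit recovered 12% of 2-fold and 94% of 4-fold changes in combination against venetoclax, with 11 false calls, and 16% and 94% in combination against CSA, with 8 false calls. At the spread without venetoclax replicate 2 it recovered 53% and 96% in the first contrast, with 24 false calls, and 81% and 99% in the second, with 38 false calls; venetoclax against CSA, where no gene was changed, had 11. False calls exceeded the nominal share in each of these 4 cases with changed genes, so calls are less secure than their adjusted p says, with all 6 libraries and without venetoclax replicate 2. In a further simulation a GC trend was put on venetoclax replicate 2 and 200 genes were changed 4-fold. Removing the GC trend moved false calls from 12 to 18 in combination against venetoclax and from 9 to 20 in combination against CSA. Recovery went from 95% to 100% and from 98.5% to 99.5%. Python 3.11.15 with pandas 2.3.3 and scipy 1.17.1 was used for tables and checks.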

Results

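Gene counts from 6 RNA-seq libraries of MV4-11 leukemia cells were compared after 24 h with venetoclax, CSA or both drugs, 2 libraries per group. Total counts were 26567900 and 28709646 with venetoclax, 27183108 and 30738957 with CSA, and 29861849 and 27056975 with the combination. The comparisons ask what each drug adds to the other in cells with mutant FLT3, and how the single agents differ.

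Venetoclax replicate 2 stood apart from the other 5 libraries. Mitochondrially encoded genes took 41.5% of its counts, against 8.01% in venetoclax replicate 1, 7.41% and 9.71% with CSA, and 8.06% and 15.2% with the combination. MT-ATP6, a subunit of the mitochondrial ATP synthase, was at 44623 unscaled CPM in that library and 1353 in its replicate, and MT-CO1, of cytochrome c oxidase, at 61322 and 22161. The 10 most abundant genes took 39.1% of its counts, against at most 15.3% elsewhere. Across nuclear genes the SD of the log2 difference between replicates was 0.71 for venetoclax, 0.33 for CSA and 0.39 for the combination. The first principal component (49.3% of variance) placed venetoclax replicate 2 at 73.9 and the others between −24.7 and −3.41. As a check for a library deposited more than once, the replicates of each group were compared with counting noise (chi-square per degree of freedom 31.6 to 848), and each was counted as its own library.

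**Figure D1:**
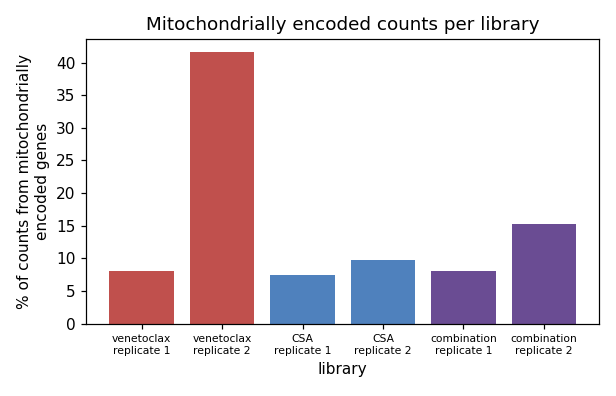
Percent of counts from mitochondrially encoded genes (vertical axis) in each of the 6 libraries (bars, coloured by treatment). Venetoclax replicate 2 is at 41.5% and the others lie between 7.41% and 15.2%.

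What CSA added to venetoclax was read from the combination against venetoclax alone. This takes the doses in the combination, which the labels do not give, to be those of the single agents. Targets of ATF4, the transcription factor of the amino acid and integrated stress response, were higher with the combination. All 33 measured members were higher, with a median log2 fold change of 1.23, and 28 passed adjusted over the list alone. SLC6A9, a glycine transporter, was at 0.678 and 0.690 CPM with venetoclax and 8.46 and 8.51 with the combination (log2 fold change 3.63, SE 0.23). ASNS, asparagine synthetase, went from 45.2 and 51.8 to 178 and 161 CPM (1.81, SE 0.16), and PSAT1, of serine synthesis, from 142 and 134 to 472 and 414 CPM (1.69, SE 0.15). SLC7A11, the cystine importer, was at 20.03 and 25.8 against 88.4 and 82.1 CPM (1.90, SE 0.19), and DDIT3, a stress-induced transcription factor, had a log2 fold change of 1.52 (SE 0.20). Camera gave the list adjusted p = 1.97e-29, and adjusted p = 0.0739 with an estimated correlation. Fry gave the list adjusted p = 0.00367. Its median was 1.25 without venetoclax replicate 2.

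Genes of DNA replication and mitosis were lower with the combination than with venetoclax. Of 43 replication genes 39 were lower (median −0.41), and 3 passed adjusted over the list alone: TYMS, thymidylate synthase (−0.83, SE 0.15), MCM10, a replication initiation factor (−0.87, SE 0.17), and RRM2, a subunit of ribonucleotide reductase (−0.67, SE 0.14). Of 32 mitosis genes 30 were lower (median −0.48), with 0 passing adjusted over the list alone by edgeR. MKI67, a marker of cycling cells, was at 1012 and 2041 CPM with venetoclax against 497 and 634 with the combination (−1.43, SE 0.35), and its value without venetoclax replicate 2 was −0.84. Camera's adjusted p was 2.08e-09 for replication and 1.21e-08 for mitosis (adjusted p = 0.0739 and 0.213 with an estimated correlation). Fry's adjusted p was 0.00558 and 0.0557. Without venetoclax replicate 2 the medians were −0.39 and −0.33, and 20 replication genes and 0 mitosis genes passed adjusted over the list alone by edgeR. With the GC trend of each library removed these counts were 20 and 12.

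Targets of NRF2, the antioxidant regulator, were higher in 17 of 18 members (median 0.33), and 5 passed adjusted over the list alone. Besides SLC7A11 these included FTH1, the ferritin heavy chain (0.86, SE 0.18), NQO1, a quinone reductase (1.18, SE 0.26), and ME1, malic enzyme (1.27, SE 0.29). Of 23 NF-kB and inflammatory genes 20 were higher (median 0.30), among them NFKB2 (0.79, SE 0.21) and ICAM1, an adhesion molecule (0.61, SE 0.20). Lysosome and autophagy genes were higher in 28 of 35 (median 0.21), for example GABARAP, which acts in autophagosome formation (0.68, SE 0.20). Heat shock proteins were lower in 15 of 18 (median −0.30), for example HSPH1 (−0.65, SE 0.18, −0.43 without venetoclax replicate 2). Adjusted over the list alone, 0 members of these last 3 lists passed edgeR's test. Camera's adjusted p was 2.1e-05, 0.00121, 0.00203 and 0.00203 in this order, and each had adjusted p = 0.213 with an estimated correlation. Fry's adjusted p was 0.0403, 0.00367, 0.0557 and 0.0642. The medians without venetoclax replicate 2 were 0.21, 0.38, 0.16 and −0.18, and adjusted over the list alone 7 NRF2 targets then passed as higher and 1 as lower, with 1 heat shock gene lower. The NRF2 and lysosome medians were 0.70 and 0.40 without venetoclax replicate 1, and that of heat shock proteins was −0.18 without combination replicate 1.

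A further 7 lists passed camera but not with every library left out in turn. Among them fry passed ER chaperones (adjusted p = 0.00367) and interferon-stimulated genes (adjusted p = 0.0319) and none of the others. ER chaperones and ERAD genes were higher in 18 of 23 (median 0.22, 0.23 without venetoclax replicate 2, adjusted p = 0.00121, and adjusted p = 0.213 with an estimated correlation). Without venetoclax replicate 1 the median was 0.29 with adjusted p = 0.0600. DNAJB9, a chaperone of the unfolded protein response, passed adjusted over the list alone (1.18, SE 0.19). Interferon-stimulated genes were higher in 23 of 34 (median 0.28, 0.27 without venetoclax replicate 2, adjusted p = 0.0102, and adjusted p = 0.213 with an estimated correlation), with a median of 0.54 and adjusted p = 0.145 without venetoclax replicate 1. Cytosolic ribosomal protein genes were higher in 35 of 37 (median 0.29, adjusted p = 0.00084, and adjusted p = 0.549 with an estimated correlation), but without venetoclax replicate 2 the median was 0.07 (adjusted p = 0.124); it was 0.58 without venetoclax replicate 1 and 0.16 without combination replicate 1. Cholesterol synthesis genes were lower in 20 of 24 (median −0.20, −0.30 without venetoclax replicate 2, adjusted p = 0.00203, and adjusted p = 0.231 with an estimated correlation). This median was −0.12 without venetoclax replicate 1 (adjusted p = 0.215) and −0.32 without combination replicate 1, and 0.02 when scaled by library size alone, which is −0.24 relative to the median of all genes. Glycolysis genes were lower in 17 of 22 (median −0.17, −0.35 without venetoclax replicate 2, adjusted p = 0.0216, and adjusted p = 0.612 with an estimated correlation). That median turned to 0.06 without venetoclax replicate 1 (adjusted p = 0.892), and was −0.11 without combination replicate 2 (adjusted p = 0.0975). Scaled by library size alone it was 0.08, which is −0.18 relative to the median of all genes (adjusted p = 0.0835). LDHA, lactate dehydrogenase A, passed adjusted over the glycolysis list alone, at 739 and 639 CPM with venetoclax and 277 and 232 with the combination (−1.44, SE 0.17). Replication-dependent histones were lower in 9 of 12 (median −0.36, −0.48 without venetoclax replicate 2, adjusted p = 0.0216, and adjusted p = 0.231 with an estimated correlation), with 1 passing adjusted over the list alone, and lost the call without 5 of the 6 libraries (adjusted p 0.0648 to 0.519; it was held only without combination replicate 2, where the median was −0.75, against −0.19 without venetoclax replicate 1, −0.22 without combination replicate 1 and −0.27 without either CSA library). The 13 mitochondrially encoded mRNAs were all lower (median −1.66, adjusted p = 0.0458, and adjusted p = 0.620 with an estimated correlation), but without venetoclax replicate 2 the median was 0.91 (adjusted p = 0.00872). It was −2.54 without venetoclax replicate 1, −1.23 without combination replicate 1 (adjusted p = 0.443), and −1.63 with the GC trend removed (adjusted p = 0.0965). Adjusted over the list alone, 0 members of the interferon, ribosomal, cholesterol and mitochondrially encoded lists passed by edgeR. There were 3 ER, 3 cholesterol, 5 glycolysis and 2 histone genes passing adjusted over the list alone without venetoclax replicate 2.

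For single genes, edgeR's quasi-likelihood test called 0 of 12690 in this comparison (smallest adjusted p 0.058), with 1372 at an unadjusted p under 0.05. DESeq2 called 294 (164 higher, 130 lower) and limma-voom 0. Without venetoclax replicate 2 edgeR called 49, of which 30 were higher and 19 lower, and without venetoclax replicate 1 it called 3426. Of the 49, in 42 venetoclax replicate 2 lay on the same side of both combination libraries as its replicate. The rule for named genes, applied to this fit after its values were seen, was met by 40 genes. The higher ones included, from the ATF4 list, SLC6A9, SLC7A11, ASNS and ALDH1L2, a mitochondrial folate enzyme (log2 fold change 1.85, SE 0.17). Outside that list they included ADM2, a peptide hormone (2.52, SE 0.18), NLRP12, an inflammasome-family receptor (2.48, SE 0.20), GAS7 (1.98, SE 0.13) and SEMA6B, a semaphorin (1.91, SE 0.20). The lower ones included PPARA, a fatty acid receptor (−3.38, SE 0.28), MDM2, the ubiquitin ligase of p53 (−2.24, SE 0.14), CREB3L2, an ER-bound transcription factor (−2.17, SE 0.11), UBE2Z, a ubiquitin-conjugating enzyme (−1.69, SE 0.11), and LDHA (−1.53, SE 0.13). TGOLN2, a trans-Golgi protein, and PSME3, a proteasome activator, also met the rule, but venetoclax replicate 2 did not share the low level of its replicate: TGOLN2 was at 73.2 and 446 CPM with venetoclax and 250 and 214 with the combination (−0.16 with all 6 libraries, 1.67 without venetoclax replicate 2).

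**Figure D2:**
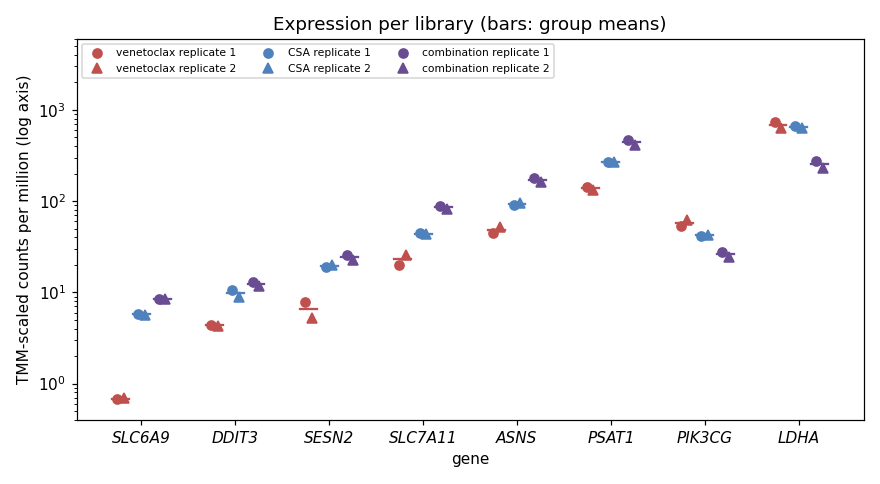
TMM-scaled CPM (log axis) of 8 genes in each library, with circles for replicate 1, triangles for replicate 2 and bars for group means. The 6 ATF4 targets on the left are lowest with venetoclax and highest with the combination, as for ASNS at 45.2 and 51.8, 89.9 and 95.0, and 178 and 161 CPM; LDHA and PIK3CG are lowest with the combination.

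What venetoclax added to CSA was read from the combination against CSA alone, with the same assumption about doses. ATF4 targets were again higher, in 31 of 33 members, but by less (median 0.35), and 3 passed adjusted over the list alone: SLC7A11 (0.95, SE 0.18), ASNS (0.88, SE 0.16) and PSAT1 (0.73, SE 0.15). All 24 cholesterol synthesis genes were lower (median −0.36). Adjusted over the list alone, 1 member passed, and DHCR7, a late enzyme of the pathway, was at −0.95 (SE 0.21). Of 22 glycolysis genes 21 were lower (median −0.27), and LDHA passed adjusted over the list alone (−1.36, SE 0.17). Of 43 DNA replication genes 39 were lower (median −0.27), for example TYMS (−0.58, SE 0.15), with 0 passing adjusted over the list alone by edgeR. Camera's adjusted p was 3.88e-11 for ATF4 targets, 3.81e-10 for cholesterol synthesis, 1.78e-06 for glycolysis and 3.8e-10 for DNA replication, and the adjusted p with an estimated correlation was 0.159, 0.159, 0.485 and 0.132. Fry's adjusted p was 0.0749, 0.0866, 0.276 and 0.00704 in the same order. Without venetoclax replicate 2 the 4 medians were 0.35, −0.36, −0.27 and −0.27, and 11, 8, 4 and 13 members passed adjusted over the list alone.

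NRF2 targets (15 of 18 higher, median 0.18, 1 passing adjusted over the list alone, SLC7A11) and NF-kB and inflammatory genes (19 of 23 higher, median 0.22) were also higher than with CSA. CCL2, a monocyte chemokine, passed adjusted over the NF-kB list alone, at 8.03 and 7.56 CPM with CSA and 16.7 and 18.8 with the combination (1.19, SE 0.22). Fatty acid synthesis genes were lower in 9 of 11 (median −0.38), and SCD, stearoyl-CoA desaturase, passed adjusted over the list alone (−0.68, SE 0.15); that median was −0.24 without combination replicate 2. All 5 measured B cell markers were lower (median −0.82), at no more than 3.02 CPM in any library; IGLL1 passed adjusted over the list alone, at 1.85 and 1.83 CPM with CSA and 0.36 and 0.291 with the combination. Camera's adjusted p was 0.000429, 0.000578, 0.00404 and 0.000492 for these 4 lists, with adjusted p = 0.265, 0.193, 0.224 and 0.265 with an estimated correlation. Fry's adjusted p was 0.215, 0.0348, 0.0749 and 0.0749. Adjusted over the list alone without venetoclax replicate 2, 5 NRF2 targets passed as higher and 1 as lower, and 6 fatty acid synthesis genes as lower and 1 as higher. ER chaperones and ERAD (18 of 23 higher, median 0.13), lysosome and autophagy (26 of 35 higher, 0.12), the nuclear-encoded respiratory chain (36 of 47 lower, −0.19), replication-dependent histones (10 of 12 lower, −0.27), FOXO-responsive genes (10 of 16 lower, −0.15) and granule proteins and progenitor markers (9 of 12 lower, −0.23) passed camera at adjusted p 0.00404, 0.00756, 0.00711, 0.0118, 0.0215 and 0.0215, with 0 members passing adjusted over the list alone by edgeR. Their adjusted p with an estimated correlation was 0.224, 0.265, 0.651, 0.265, 0.384 and 0.434. Among them fry passed only ER chaperones and ERAD (adjusted p = 0.0348). In the fit without venetoclax replicate 2, 3 FOXO-responsive genes, 3 granule genes and 1 histone gene passed as lower, adjusted over the list alone. Each lost the call when at least 1 library was left out: ER chaperones without combination replicate 1 (median 0.14, adjusted p = 0.0758), lysosome without CSA replicate 2 or combination replicate 2 (0.0743 and 0.0814), respiratory chain without CSA replicate 1 or combination replicate 2 (0.280 and 0.604), histones without any library but combination replicate 2 (0.108 to 0.241), FOXO-responsive genes without either venetoclax library, CSA replicate 1 or combination replicate 2 (0.0568 to 0.0933, medians −0.15 to −0.10), and granule proteins without CSA replicate 2 or either combination library (0.0649 to 0.120, medians −0.34 to −0.19). The lysosome median was 0.07 without CSA replicate 2 and 0.11 without combination replicate 2. That of the respiratory chain was −0.11 and −0.29 without CSA replicates 1 and 2, and −0.36 and −0.07 without combination replicates 1 and 2. For histones it was −0.02 without CSA replicate 1, −0.17 and −0.55 without combination replicates 1 and 2, and −0.25 to −0.22 without the others. Scaled by library size alone, ER chaperones, lysosome and granule proteins had adjusted p = 0.0633, 0.156 and 0.156, with medians of 0.10, 0.07 and −0.27.

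EdgeR's test called 0 single genes here (462 at an unadjusted p under 0.05, smallest adjusted p 0.129), against 56 by DESeq2 and 1 by limma-voom. With either venetoclax library left out it called 24, which were 13 higher and 11 lower without venetoclax replicate 2. Of those 24, 22 met the naming rule. XPO4, a nuclear export receptor (1.21, SE 0.08), CYP1B1, a cytochrome P450 (1.78, SE 0.15), THBS1, thrombospondin (1.66, SE 0.15), and CHI3L1, a secreted glycoprotein (1.18, SE 0.09), were higher; PPARA (−3.02, SE 0.26), CREB3L2 (−2.29, SE 0.10), MDM2 (−2.11, SE 0.12), UBE2Z (−1.77, SE 0.09), RASAL2 (−1.65, SE 0.11) and LDHA (−1.36, SE 0.12) were lower. BCL2L2, a BCL2 relative, had 3.34 (SE 0.19), but it overlaps another gene on its strand, so its counts are uncertain.

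The combination differed from both single agents in the same direction for 13 genes without venetoclax replicate 2, 5 higher and 8 lower, and for 0 with all 6 libraries by edgeR (301 at an unadjusted p under 0.05, where simulated unchanged groups gave a mean of 140, and 36 by DESeq2). The 8 lower were PPARA, MDM2, CREB3L2, UBE2Z, LDHA, CLEC2D, YIPF6 and ZNF548, which overlaps another gene on its strand. Of the 5 higher, ENSG00000269693 also overlaps another gene on its strand (5.45 against venetoclax and 5.12 against CSA without venetoclax replicate 2). For 3 of the 13 venetoclax replicate 2 was not on the side of its replicate: TGOLN2 (446 CPM, against 250 and 214 with the combination), PCNP (144 CPM, against 116 and 133) and ZNF548 (4.72 CPM, against 6.24 and 6.72). Of the 13, 10 sat at 2 separate levels in the 5 libraries with little spread within each, a pattern also seen between replicates of a group in other genes. Since a call needs little spread within groups, this share is in part set by the test. PPARA, ZNF548 and ENSG00000269693 had a mean CPM under 20 and were not examined for this pattern. PPARA was at 21.3 and 14.8 CPM with venetoclax, 16.4 and 16.6 with CSA, and 2.52 and 1.53 with the combination. MDM2 was at 64.2 and 28.7 CPM with venetoclax, 58.8 and 57.9 with CSA, and 12.5 and 14.6 with the combination. CREB3L2 was at 120 and 105, 122 and 136, and 26.3 and 26.6 CPM. Among the higher, SEMA6B was at 26.4 and 13.3, 33.0 and 25.8, and 103 and 95.0 CPM, and CHI3L1 at 150 and 160, 169 and 176, and 371 and 414 CPM. Unchanged groups that share the combination libraries gave a mean overlap of 1.5 genes and at most 6 in 40 draws, and independent lists would share 0.030 higher and 0.016 lower. The draws already share the combination libraries, so the excess over them does not come from that sharing as simulated. Genes were drawn independently, with no GC trend or effect of replicate number, so part of this excess may still be technical.

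The single agents were compared directly. ATF4 targets were lower with venetoclax than with CSA in 32 of 33 members (median −0.83), and 22 passed adjusted over the list alone. SLC6A9 was at 0.678 and 0.690 CPM with venetoclax and 5.75 and 5.70 with CSA (−3.06, SE 0.22). SESN2, a stress-induced regulator of mTOR complex 1 (−1.57, SE 0.25), ATF3, a stress-response transcription factor (−1.68, SE 0.28), and PSAT1 (−0.96, SE 0.15) were lower too. Mitosis genes were higher with venetoclax in 26 of 32 (median 0.42), for example CDK1, the mitotic kinase (0.57, SE 0.15), and ribosomal protein genes were lower in 34 of 37 (median −0.37); adjusted over the list alone, 0 members of either passed by edgeR. Camera's adjusted p for the 3 lists was 2.26e-22, 1.97e-06 and 4.4e-05, with adjusted p = 0.147, 0.440 and 0.570 with an estimated correlation. Fry's adjusted p was 0.0182, 0.119 and 0.295. Without venetoclax replicate 2 the medians were −0.92, 0.20 and −0.14, and that of ribosomal protein genes was −0.70 without venetoclax replicate 1.

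Another 6 lists passed camera only with certain libraries present. Fry passed none of them, with the smallest adjusted p at 0.0508 for interferon-stimulated genes. The 13 mitochondrially encoded mRNAs were all higher with venetoclax (median 2.33, adjusted p = 0.00157, and adjusted p = 0.646 with an estimated correlation), but without venetoclax replicate 2 the median was −0.17 (adjusted p = 0.430). Genes of the KMT2A-AFF1 fusion programme, such as the transcription factor gene MYB, were higher in 12 of 13 (median 0.56, adjusted p = 0.0209, and adjusted p = 0.616 with an estimated correlation). Their median was 0.04 without venetoclax replicate 2 (adjusted p = 0.524), and it was 0.93 without venetoclax replicate 1 and 0.64 without CSA replicate 2 (adjusted p = 0.0518). Nuclear-encoded respiratory chain genes were lower in 38 of 47 (median −0.21, adjusted p = 0.0158, and adjusted p = 0.652 with an estimated correlation), with a median of −0.03 without venetoclax replicate 2 (adjusted p = 0.888), −0.12 without CSA replicate 1 (adjusted p = 0.160) and −0.42 without venetoclax replicate 1. NRF2 targets were lower in 15 of 18 (median −0.25, adjusted p = 0.0214, and adjusted p = 0.538 with an estimated correlation), with −0.08 without venetoclax replicate 2 (adjusted p = 0.122), −0.53 without venetoclax replicate 1, and −0.21 without CSA replicate 2 (adjusted p = 0.0925). Interferon-stimulated genes were lower in 24 of 34 (median −0.26, −0.22 without venetoclax replicate 2, adjusted p = 0.0214, and adjusted p = 0.440 with an estimated correlation). They lost the call with a replicate block (median −0.27, camera adjusted p = 0.0721). Their median was −0.41 without venetoclax replicate 1 (adjusted p = 0.241) and −0.32 without CSA replicate 2 (adjusted p = 0.0752). Heat shock proteins were higher in 15 of 18 (median 0.15, 0.13 without venetoclax replicate 2, adjusted p = 0.0214, and adjusted p = 0.440 with an estimated correlation). Their adjusted p was 0.132, 0.0803 and 0.0518 without venetoclax replicate 1, CSA replicate 1 and CSA replicate 2, with medians of 0.26, 0.13 and 0.18. Scaled by library size alone the median was −0.18, which is 0.13 relative to the median of all genes (adjusted p = 0.204). Adjusted over the list alone, 1 NRF2 target, SLC7A11, passed and 0 members of the other 5 lists did by edgeR.

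EdgeR called 0 single genes between the single agents (609 at an unadjusted p under 0.05, smallest adjusted p 0.146). DESeq2 called 63 and limma-voom 0. Without venetoclax replicate 1 edgeR called 4385, and without venetoclax replicate 2 it called 0.

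**Figure D3:**
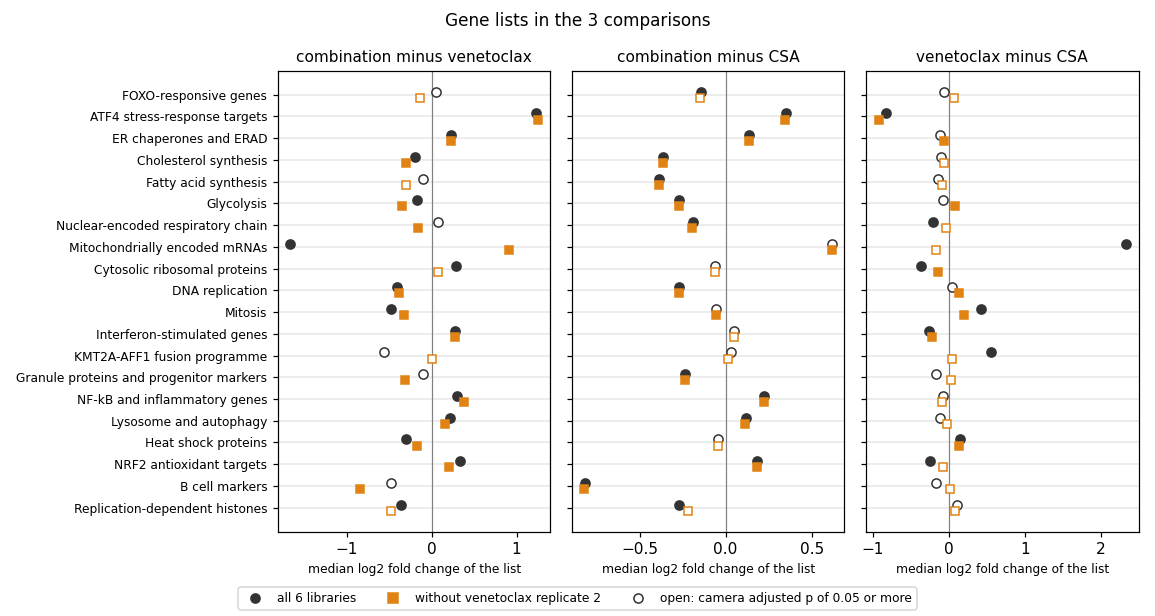
Median log2 fold change (horizontal axis) of each list that passed camera in at least 1 comparison, in 3 panels. Circles are all 6 libraries and squares leave out venetoclax replicate 2, filled where camera's adjusted p was under 0.05. ATF4 targets are at 1.23, 0.35 and −0.83; the mitochondrially encoded mRNAs change sign in the left and right panels when the library is left out. Scaling by library size alone, which moved the median of all genes, turned the medians of cholesterol synthesis, glycolysis, fatty acid synthesis and granule proteins (left panel), of the KMT2A-AFF1 programme (middle panel), and of heat shock proteins, DNA replication and histones (right panel); relative to all genes each kept its sign. Upper quartile scaling turned DNA replication (right panel) too, and removing the GC trend turned the KMT2A-AFF1 programme (middle panel) and B cell markers (right panel).

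Genes of the drugs' own targets and of PI3K signalling were set in advance. BCL2, the target of venetoclax, was at 74.3 and 79.6 CPM with venetoclax, 68.1 and 65.8 with CSA, and 60.8 and 53.8 with the combination (combination against venetoclax −0.43, SE 0.15, adjusted p = 0.420 by edgeR). Its relatives MCL1 and BCL2L1 differed by −0.10 (SE 0.14) and 0.07 (SE 0.16), and BCL2A1, at no more than 1.91 CPM, by −0.14 (SE 0.38). These values were −0.03, 0.0028 and 0.19 without venetoclax replicate 2. Against CSA, BCL2L2 and BCL2L11, the pro-apoptotic BIM, passed adjusted over the BCL2 family list alone. BCL2L11 was at 10.1 and 6.63 CPM with CSA and 59.6 and 21.2 with the combination (2.27, SE 0.53), and it did not pass without venetoclax replicate 2 (2.27, SE 0.59), when 1 member, BCL2L2, did. Between the single agents BCL2L2, the overlapping gene, passed adjusted over the list alone as higher with venetoclax (3.04, SE 0.29). Camera gave the family adjusted p = 0.233, 0.108 and 0.864 in the 3 comparisons. The second passed with the GC trend removed (adjusted p = 0.0391), without CSA replicate 1 (0.0487) and without combination replicate 2 (0.00765), with medians of 0.07, 0.08 and 0.13 against 0.02, and had adjusted p = 0.629 with an estimated correlation.

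FLT3 was at 838 and 926, 860 and 871, and 894 and 861 CPM in the 3 groups, and MYC differed by −0.16 (SE 0.24) between combination and venetoclax, a value that turned to 0.13 (SE 0.18) without venetoclax replicate 2. The 33 PI3K-AKT-mTOR components did not pass camera in any comparison (adjusted p = 0.149, 0.496 and 0.356). Fry gave adjusted p = 0.00443, 0.0348 and 0.0182. Their medians were −0.11, −0.02 and 0.20, and scaled by library size alone the first and last were 0.13 and −0.12, which is −0.13 and 0.20 relative to the median of all genes. They were −0.12, −0.02 and 0.06 without venetoclax replicate 2, and with the GC trend removed the last was 0.02. PIK3CG, the gamma catalytic subunit of PI3K, passed adjusted over the list alone against venetoclax, at 53.5 and 62.7 CPM with venetoclax, 41.8 and 42.3 with CSA and 27.5 and 24.6 with the combination (−1.16, SE 0.17, adjusted p = 0.139 over all genes by edgeR). The list had 2 members lower and 1 higher adjusted over the list alone without venetoclax replicate 2. PIK3CD, AKT1 and MTOR differed by 0.18 (SE 0.28), 0.35 (SE 0.29) and 0.02 (SE 0.18), and by −0.17, 0.0034 and −0.15 without venetoclax replicate 2. DDIT4, an inhibitor of mTOR complex 1 and an ATF4 target, was at 7.05 and 2.65 CPM with venetoclax, 27.4 and 19.96 with CSA, and 34.1 and 25.6 with the combination (2.60, SE 0.49, 2.08 without venetoclax replicate 2). RCAN1, a calcineurin-responsive gene, differed by −0.21 (SE 0.20) against venetoclax, −0.40 without venetoclax replicate 2, and −0.26 (SE 0.20) against CSA. ABCB1, the efflux transporter that CSA blocks, had a count of 0 in each library.

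On GRCh38 (GENCODE 29) SLC6A9 (ENSG00000196517) lies on chromosome 1 at 43991500 to 44031467, ASNS (ENSG00000070669) on chromosome 7 at 97852118 to 97872542, PSAT1 (ENSG00000135069) on chromosome 9 at 78297143 to 78330093 and SLC7A11 (ENSG00000151012) on chromosome 4 at 138164097 to 138242349. LDHA (ENSG00000134333) lies on chromosome 11 at 18394388 to 18408425, PIK3CG (ENSG00000105851) on chromosome 7 at 106865278 to 106907145 and MDM2 (ENSG00000135679) on chromosome 12 at 68808176 to 68850686. Values are sums over whole genes, so no exon or UTR is singled out.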

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

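The tests with DESeq2 without venetoclax replicate 2, with a block without that library, with library quality weights and with the GC trend removed were chosen only after the results were seen. Counts of called genes (0 in each comparison with edgeR) are given for combination against venetoclax, combination against CSA and venetoclax against CSA in this order. DESeq2 called 294, 56 and 63, and 448, 227 and 100 without venetoclax replicate 2. With no low-count filter there were 15, 4 and 2. Limma-voom called 1 in the second comparison and 43 there with quality weights, and a fit of only the 4 libraries compared called 24 there. Removing the GC trend, a step that added false calls in simulation, gave 28 in the first comparison. Leaving out single libraries gave 0 to 3426, 0 to 24 and 0 to 4385; the highest of the first and last came without venetoclax replicate 1, when the group rested on replicate 2. Genes shared against both agents numbered 36 by DESeq2 and 0 to 15 with single libraries left out. Other settings gave 0 in each comparison by edgeR or limma-voom, with 144 to 1855 genes at an unadjusted p under 0.05 outside the leave-outs. The cause of these differences was not tested, beyond the number of libraries or genes in each fit.

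The replicate numbers pair the groups by number only. In each group replicate 2 had the higher share of mitochondrially encoded counts. It was 41.5% against 8.01% with venetoclax, 9.71% against 7.41% with CSA and 15.2% against 8.06% with the combination. The difference of replicate 2 from replicate 1 fell with GC content in each group (Spearman rho −0.637, −0.312 and −0.232). An effect shared by replicate number is therefore possible, and the main fit has no block for it. Deviations of same-numbered libraries correlated across genes at 0.192, 0.252 and 0.164, from 2 numbers. With a replicate block edgeR called 0, 0 and 0, and without venetoclax replicate 2 the block gave 229, 72 and 16.

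Lists past camera numbered 14, 14 and 9, and 0, 0 and 0 with an estimated correlation, and fry passed 9, 4 and 4. The estimated correlation was under the preset 0.01 for some lists, for example −0.016 for DNA replication. Camera's adjusted p for that list against venetoclax still went from 2.08e-09 to 0.0739. Its loss therefore does not come from a correlation above the preset. Camera with an estimated correlation also refers its statistic to the 3 residual degrees of freedom of the fit. Its p is thus not a measure of correlation between genes alone. How much of the loss comes from this was not tested. With the GC trend removed camera also passed B cell markers against venetoclax (adjusted p = 0.0344), the BCL2 family and mitosis against CSA (0.0391 and 0.00303), and ER chaperones and DNA replication between the single agents (0.0196 and 0.000779). Further lists passed camera without venetoclax replicate 2 and are given with their medians. Respiratory chain (−0.16), granule proteins (−0.31) and B cell markers (−0.85) were lower against venetoclax. Against CSA mitochondrially encoded mRNAs were higher (0.62) and mitosis lower (−0.06). Between the single agents ER chaperones were lower (−0.07), and glycolysis (0.08), DNA replication (0.13) and monocyte genes (0.11) higher. Without venetoclax replicate 1 instead, the respiratory chain median against venetoclax was 0.30. The glycolysis median between the single agents was then −0.33, so both had the opposite sign. For venetoclax against CSA 5 to 10 passed with single libraries left out, the lowest without CSA replicate 2. Of the counts of genes and lists, 75 values under alternatives were within 1.5 times the reported one and 31 were not. For named genes and list members 9034 values kept direction and side of the threshold, 669 passed only under the alternative, 4 reversed with a call, and 328 that were called in neither fit did not keep their sign (median size 0.09 as reported; 48 of them with library size alone and 45 without venetoclax replicate 2). TGOLN2, combination against venetoclax, ranged from −0.94 to 1.67 with single libraries left out (highest without venetoclax replicate 2), and was at 1.67 by DESeq2 without it and 1.76 with the block without it, and PSME3, venetoclax against CSA, ranged from −1.54 to 0.68 (highest without venetoclax replicate 1). The simulated recovery of 12% of 2-fold changes in combination against venetoclax shows what the spread with all 6 libraries can miss.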

Other observations

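Of the tests below, those of transcript length, of GC content, of the ATF4 list without venetoclax replicate 2 and of that list's GC content were set before their results were seen; the others were chosen only after the result was seen.

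FOXO-responsive genes did not pass camera against venetoclax (adjusted p = 0.211, median 0.05, with the test on the lower side), yet 4 of 16 were lower with the combination adjusted over the list alone (0 over all genes by edgeR). The median was −0.14 and 2 passed without venetoclax replicate 2. The 4 were SESN3, a sestrin (log2 fold change −1.97, SE 0.35, −1.44 without venetoclax replicate 2), CCNG2, an atypical cyclin (−0.77, SE 0.21), BNIP3, a mitophagy receptor (−1.15, SE 0.28), and BCL6, a transcriptional repressor at no more than 2.33 CPM (−1.40, SE 0.39). TLR4, the lipopolysaccharide receptor, passed adjusted over the monocyte list alone (−1.13, SE 0.18), at 24.3 and 28.1 CPM with venetoclax and 12.3 and 11.6 with the combination, while that list had camera adjusted p = 0.0577 (median −0.21) and fry adjusted p = 0.0478. Camera passed the list with a replicate block (adjusted p = 0.0465, median −0.19). Its median was −0.28 without either CSA library or combination replicate 1. Between the single agents the camera and fry adjusted p of the list were 0.0591 and 0.0367 (median 0.22). Relative to all genes the medians of −0.21 and 0.22 kept their sign when scaled by library size alone. Lists of FLT3-STAT5 targets, p53 targets, MYC and ribosome biogenesis, calcineurin and NFAT, ERK output, class II antigen presentation and drug efflux did not pass camera in any comparison (smallest adjusted p 0.0806). Of these, fry passed drug efflux against venetoclax (adjusted p = 0.0478, median 0.11, −0.0080 without venetoclax replicate 2). Markers of other cell types were scarce. Of T and NK cell markers 3 were measured, of epithelial and stromal markers 3, and of erythroid and megakaryocytic markers 2.

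Venetoclax replicate 2 stood apart from all other libraries. A plain uptake of counts by mitochondrial RNA is argued against, since with those genes removed the SD of the difference between its nuclear genes and its replicate's was still 1.90 times the larger SD of the other pairs (0.69 against 0.36 over 9860 genes, a narrower set than that of the SDs given with the depth of the libraries). Replicate 1, with the same venetoclax exposure, had 8.01% mitochondrial counts, between the 7.41% and 9.71% of the CSA libraries. Exposure thus did not go with a high share in both venetoclax libraries. Whether it contributed in replicate 2 cannot be decided, since the test rests on 1 venetoclax library, has no untreated library beside it and was set after the values were seen. The difference between the venetoclax replicates followed GC content across nuclear genes (Spearman rho −0.637, against −0.312 and −0.232 in the other pairs), so a GC bias of that library may account for part of it. The sign was the same in each pair, so part of the trend may go with the replicate number and not with that library alone. A GC bias of the library leaves a part unexplained. It is not the whole cause, since the median of the mitochondrially encoded mRNAs, venetoclax minus CSA, was 2.16 once GC trends were removed and 2.33 before. Transcript length (rho 0.264, against 0.142 and 0.0810) stays open.

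The rise of ATF4 targets from venetoclax to the combination may reflect CSA exposure. All 33 members were higher in the mean of CSA alone than in venetoclax replicate 1, and 31 were higher still with the combination. Venetoclax replicate 2 as the source is argued against by a median of 1.25 without it, and GC content by a median of 1.16 after each gene's GC bin was taken off, against 1.23. The list was not lower with the combination than with CSA alone (31 of 33 higher, median 0.35). Whether CSA alone raised the list, or venetoclax alone lowered it, against untreated cells stays open, because no untreated library was analysed here.

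Some genes sat at 2 separate levels with little spread within each. Of 7159 nuclear genes with a mean CPM of 20 or more, 150 did so without venetoclax replicate 2, and for 109 the levels differed between replicates of a group: CYBRD1 was at 11.3 and 43.4 CPM with CSA and at 13.4 and 40.3 with the combination. Reads shared between overlapping genes are a possible explanation that cannot be told apart here, since 16.5% of the 109 overlapped a gene on their strand against 9.93% of all, and the overlap annotation does not show how reads were assigned. The levels parted the combination from the single agents in 22 genes, including MDM2, CREB3L2 and UBE2Z, against at most 8 for the 9 other splits of the 5 libraries into 2 and 3, too few splits to give a share under 0.05. Combination replicate 2 alone was set apart in 24 genes, and the other single libraries in 12 to 16. The 22 genes are therefore not the highest number over all splits. With all 6 libraries the levels parted the combination from the single agents in 10 genes, against at most 6 for any other pair of libraries. Combination replicate 2 alone was then set apart in 11 and venetoclax replicate 2 alone in 397. No biological explanation was tested.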
